A study of Mus musculus with 10 samples.

How the data were processed

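Gene expression was measured in CD4 T cells sorted from digests of the proximal small intestine of Bhlhe40 wild-type and knockout mice, naive or infected a second time with Heligmosomoides polygyrus bakeri, on 10 single-colour arrays. The groups were taken from the sample titles: naive wild type (n = 2), naive knockout (n = 2), rechallenged wild type (n = 3) and rechallenged knockout (n = 3). Per the labels, the authors processed the arrays with RMA, and the deposited values are on the log2 scale, as their range of 2.35 to 14.2 over the arrays also shows. The software, its version and its settings for RMA are not stated. Array medians ran from 5.84 to 5.91, and the arrays' number limits the precision.

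The value table held 26836 probe sets. By the given annotation table, dated 2016, 21549 of them belong to 1 gene, 1523 to several and 3764 to none. Only the probe sets of 1 gene were tested, 21477 of them matched to the reference gene table by Entrez number, with 0 symbols updated. Where a gene had several probe sets (885 genes), the one with the highest mean over all 10 arrays stood for it, which gave 19898 genes. No filter on dim probe sets was used. The other probe sets were fitted apart and enter no comparison.

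A limma model (version 3.58.1, with statmod 1.5.0 on R 4.3.3) with 1 mean per group was fitted to all 10 arrays by lmFit, with eBayes moderation, and gave 5 contrasts: knockout minus wild type in rechallenged and in naive mice, rechallenge minus naive in wild type and in knockout, and the difference between the genotype effects (the interaction). The moderated tests are two-sided, and p-values were adjusted by Benjamini and Hochberg over all tested genes within a contrast, with a threshold of 0.05. Intervals are 95% intervals of the moderated test. A change counted as 2-fold at an absolute log2 value of at least 1. No replicate block was used: the replicate numbers do not pair the samples, since the correlations of the same-numbered arrays' deviations from their group means stayed under 0.1. Tables and plots were made with python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

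There were 26 gene lists: T cell cytokines and ligands, the CSF2RB family, the Th2, Th1 and cytotoxic, Th17, Treg and Tfh programs, naive and central memory genes, tissue residency genes, TCR and AP-1 immediate early genes, cell cycle, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, circadian clock and type I interferon response genes, T cell identity genes, heat shock and dissociation genes, and markers of B cells, plasma cells, macrophages and dendritic cells, eosinophils and neutrophils, mast cells and basophils, intestinal epithelium, stroma and endothelium, and CD8, gamma delta T and NK cells. Each list was tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the 26 lists of a contrast, and again with an estimated correlation and with fry. Members past the threshold were counted over all genes and adjusted over the list alone. A list with under 3 measured members would have been left out, which none was. Genes sit on more than 1 list in places: 17 of the 31 cytokines and ligands and 5 of the 18 Th2 program genes are also on another list, while 0 of the 13 mast cell and basophil markers, 0 of the 14 eosinophil and neutrophil markers and 0 of the 10 plasma cell markers are. All 10 arrays had signals over their own median for 0 of the mast cell and basophil markers, 0 of the eosinophil and neutrophil markers, 2 of the 29 epithelium markers and 13 of the 13 T cell identity genes.

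Genes were named by a rule. Bhlhe40 is always named. For each contrast the rule takes the 8 largest rises and the 8 largest falls among genes past the threshold whose groups do not overlap (the interaction without that condition), leaving out predicted genes, small RNAs and antigen receptor segments, which are given as a count. Where fewer than 5 genes pass in a direction, it takes the 5 largest at an unadjusted p under 0.01, stated as not past the threshold. For each list and contrast it takes up to 4 members with the smallest p. In the genotype comparison of rechallenged mice and the infection comparison of wild type it also takes a fixed list of names, among them Il4, Il5, Il13, Il9, Il3, Csf2, Il10, Ifng, Il17a, Il21, Gata3, Tbx21, Foxp3, Bcl6, Il1rl1, Csf2rb and Bhlhe41, of which Il1rl1 had no probe set of its own gene alone and was not analysed here. Genes named outside the rule are said to be so.

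The comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were a fit with only the arrays compared, a replicate block, a repeated quantile normalization, centring each array on its median, leaving out genes that are not above their array's median on at least 2 arrays, the mean of a gene's probe sets, trended and robust eBayes, array weights, a minimum log2 change of 1, and leaving out each array in turn; where this leaves 1 array in a group, the lone array is assumed to vary like the other groups. Chosen after seeing the data were leaving out the naive knockout array 2, which has the highest macrophage and epithelium markers, leaving out this array and the rechallenged wild-type array 2, and fitting the arrays' means over the epithelium and plasma cell lists as covariates.

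The code was tested on simulated data with each gene's real mean, 1 fitted spread per gene shared by all groups, and independent noise. In these data 100 genes were changed by 1 and 100 by 2 on the log2 scale. It recovered 87% and 97% of them in the genotype comparison of rechallenged mice, with 7 false calls, 64% and 98% in that of naive mice, with 10, 79% and 99% in the infection comparison of wild type, with 7, and 75% and 98% in that of knockout, with 6. A simulated list of 20 genes shifted by 1 passed camera, and 0 of 25 lists without a shift did. These lists were random genes with independent noise, so they do not test false list calls where members move together. For the covariance between comparisons that share arrays, 100 data sets without any change were simulated from the fitted spreads. The covariance of the 2 changes was also taken with the rechallenged wild-type arrays split 1 against 2, in all 6 ways, so that no array entered both. The 10 splits of the 6 rechallenged arrays into 3 and 3 were each fitted as the real groups were. For 1 test in the closing section, tested genes were ordered along the chromosomes by the reference gene table.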

Results

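CD4 T cells sorted from digests of the proximal small intestine of mice were measured on 10 single-colour expression arrays with biotin-labelled total RNA. The mice carried an intact Bhlhe40 gene (wild type) or a knocked-out one (knockout). Bhlhe40 encodes a basic helix-loop-helix transcription factor. The groups were naive wild type (n = 2), naive knockout (n = 2), rechallenged wild type (n = 3) and rechallenged knockout (n = 3). Rechallenge stands for a secondary infection with the intestinal roundworm Heligmosomoides polygyrus bakeri. Array medians lay between 5.84 and 5.91 on the log2 scale, and the number of arrays limits the precision. The labels number the replicates without stating whether the samples are separate mice, so the p-values measure the spread between samples, which is possibly technical. Changes are given on the log2 scale with their standard error (SE), group means with their standard deviation (SD), and genes by the symbol of the array's annotation table.

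On the first principal component, which held 32.5% of the variance, rechallenged wild-type arrays lay between 26.4 and 38.2, rechallenged knockout arrays between -4.42 and -2.87 and naive arrays of both genotypes between -25.6 and -21.4. The next component (15.2%) set the naive knockout arrays apart from each other, at 30.3 for replicate 1 and -31.9 for replicate 2.

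Bhlhe40 itself, read by probe set 10540472, had a mean signal of 9.88 ± 0.076 (SD, n = 2) in naive wild-type cells and 9.45 ± 0.0074 (SD, n = 2) in naive knockout cells. In rechallenged mice it was 11.52 ± 0.21 (SD, n = 3) in wild type and 9.92 ± 0.15 (SD, n = 3) in knockout. Its signal was lower in knockout cells after rechallenge (-1.60 ± 0.13, adjusted p = 0.00151, 3.02-fold), with all 3 knockout arrays under all 3 wild-type arrays. The naive difference did not pass (-0.42 ± 0.16, adjusted p = 0.652). With infection it rose in wild type (1.64 ± 0.15, adjusted p = 3.82e-04) and did not pass in knockout (0.47 ± 0.15, adjusted p = 0.333). The difference between these changes had an adjusted p of 0.0781 (-1.18 ± 0.21). The labels do not state whether this probe set lies in the deleted part of the gene, so a remaining signal in knockout cells does not measure the protein. With the mean signals of the epithelium and plasma cell lists as covariates, the difference in rechallenged mice was -1.50 at an adjusted p of 0.291.

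The central comparison asked which genes differ between knockout and wild-type CD4 T cells during the rechallenge. Knockout cells had less message for several helper cytokines and for genes such as Nlrp3 and Alox5, while Il4 did not pass. Il5, the cytokine that drives eosinophils, was 4.25-fold lower (-2.09 ± 0.22, adjusted p = 0.00288), and Il13, which acts on goblet cells and smooth muscle, 2.97-fold lower (-1.57 ± 0.20, adjusted p = 0.00727). Csf2, which encodes GM-CSF, was 4.68-fold lower (-2.23 ± 0.28, adjusted p = 0.00727) and Il6 10.3-fold lower (-3.37 ± 0.49, adjusted p = 0.0137). These 4 did not pass with the mean signals of the epithelium and plasma cell lists as covariates, an alternative chosen after seeing the data. There Il5 had -1.06 ± 0.30 (adjusted p = 0.438), Il13 -0.93 ± 0.37 (adjusted p = 0.624), Csf2 -1.06 ± 0.45 (adjusted p = 0.657) and Il6 -3.47 ± 1.13 (adjusted p = 0.489). The epithelium mean was higher on every knockout array than on every wild-type array, so this fit separates it from the genotype only poorly. Il10 was 2.79-fold higher (1.48 ± 0.20, adjusted p = 0.00862). It lay at 9.54 (naive 9.52) and in wild type at 8.06 (naive 9.53). Also higher were transcripts typical of naive and follicular helper T cells (Lef1, Cxcr5), mucous glands (Tff2), smooth muscle (Acta2) and plasma cells (Jchain).

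In all, 276 of 19898 genes passed the threshold of limma's moderated test between the 3 knockout and 3 wild-type arrays, 127 higher and 149 lower in knockout, and 159 of them by at least 2-fold. The groups' values did not overlap for any of the 276, compared with 24.5% of all genes without overlap and 10% by chance. The 8 largest decreases that the rule for naming takes were those of Slc17a6 (-3.42 ± 0.28), a vesicular glutamate transporter, Il6, Frzb (-3.26 ± 0.33), a secreted Wnt antagonist, and Nlrp3 (-2.98 ± 0.20), the inflammasome sensor. They also included the chemokine receptor Ccr1 (-2.86 ± 0.30), Alox5 (-2.84 ± 0.24), the enzyme that starts leukotriene synthesis, the decoy receptor Il1r2 (-2.76 ± 0.30) and the scavenger receptor Olr1 (-2.60 ± 0.42), with adjusted p from 5.99e-04 to 0.0199. The 8 largest increases were those of Jchain (5.04 ± 0.82), the joining chain of polymeric antibodies, Sparcl1 (4.16 ± 0.22), and the mucous gland products Tff2 (3.73 ± 0.63) and Gkn3 (3.53 ± 0.71). Smooth muscle actin Acta2 (2.77 ± 0.38), Dapl1 (2.56 ± 0.51), the signalling chain of the IL-6 receptor Il6st (2.33 ± 0.21) and Ephx1 (2.25 ± 0.22) completed them. Their adjusted p lay between 1.32e-04 and 0.0467. For Frzb, Nlrp3, Ccr1, Olr1, Jchain, Sparcl1, Gkn3, Acta2 and Dapl1 the lower group mean lay below the array medians (4.04 for Nlrp3 and 4.68 for Sparcl1), so their sizes and order are not exact. Another 6 genes that passed were predicted genes, small RNAs or receptor segments, which the rule does not name.

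Of the 31 measured T cell cytokines and ligands, 1 rose (Il10, higher in knockout), 7 fell and 23 did not pass. Adjusted over the list alone 6 rose and 11 fell. The list's median was -0.35 (camera adjusted p = 0.0176, and 0.295 with an estimated correlation). Without wild-type replicate 2 it was -0.37 (camera adjusted p = 0.0582). Besides Il5, Il13, Csf2 and Il6, the falls were those of the growth factor Il2 (-1.14), Tnfsf11 (-0.78), which encodes RANKL, and Cd40lg (-0.94), the ligand with which T cells help B cells. These last 3 lie outside the naming rule and were chosen after their values were seen. Of 18 Th2 program genes 5 fell and 13 did not pass. With p adjusted over the list alone, 1 rose and 8 fell. The program's median was -0.38 and its mean -0.71 (camera adjusted p = 4.52e-05, and 0.0945 with an estimated correlation). Without wild-type replicate 3 the median was -0.60. The chemokine receptor Ccr8 was among the falls (-0.80 ± 0.12, adjusted p = 0.0137). Gata3, the Th2 master regulator, did not pass (-0.52 ± 0.17, adjusted p = 0.195). Il4 differed by 0.030 ± 0.22 (adjusted p = 0.961) and Il3 by 0.47 ± 0.35 (adjusted p = 0.555). Of the 8 CSF2RB family cytokines and receptors, the same Csf2 and Il5 fell and 6 did not pass, the same as when adjusted over the list alone. For the CSF2RB family the median was -0.026, with camera adjusted p = 0.208 and adjusted p = 0.384 with an estimated correlation. The shared receptor chain Csf2rb differed by 0.27 ± 0.22 (adjusted p = 0.594).

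**Figure D1:**
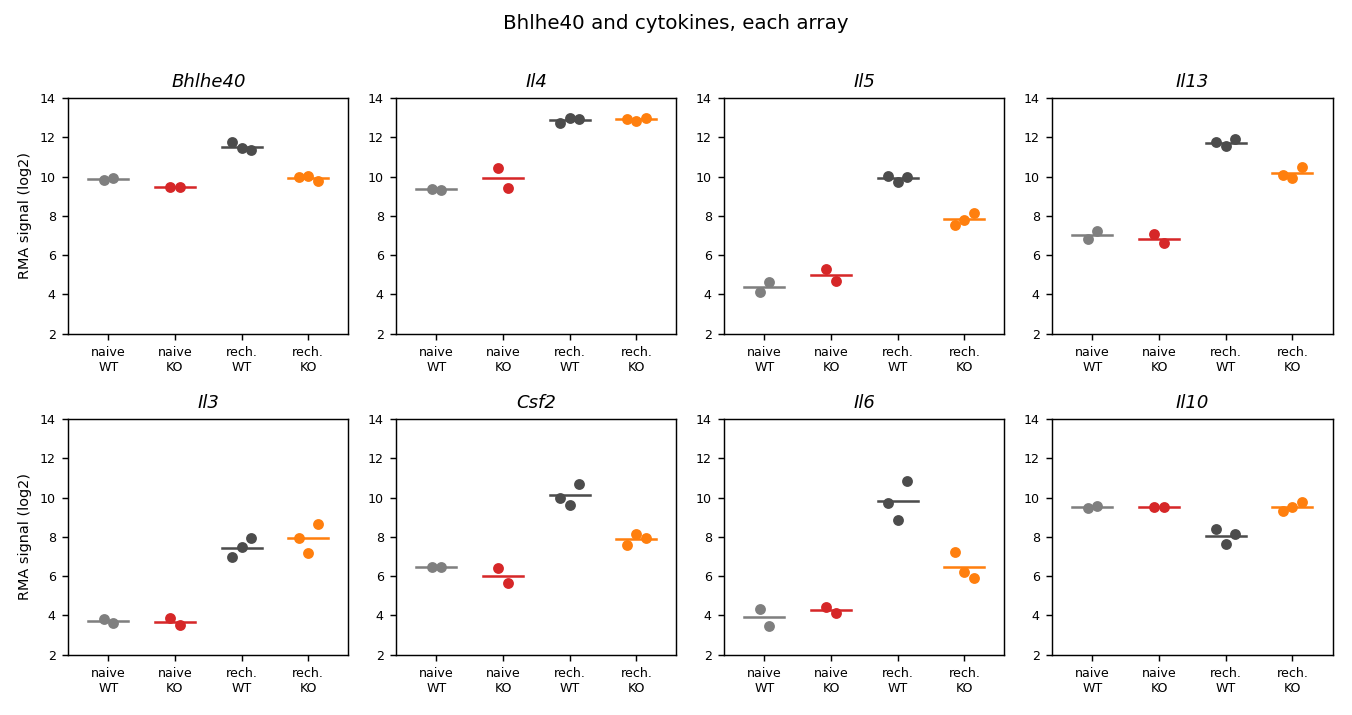
Each point is 1 array's RMA signal (log2, vertical axis) for Bhlhe40 and 7 cytokines, with the 4 groups on the horizontal axis (rech., rechallenge, WT, wild type, KO, knockout) and lines at the group means. Il5 averaged 7.82 in rechallenged knockout and 9.91 in rechallenged wild type, while Il4 averaged 12.91 and 12.88.

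In the list of 21 glycolysis and hypoxia genes 4 fell and 17 did not pass, and adjusted over the list alone 6 fell. For glycolysis and hypoxia genes the median was -0.40, with camera adjusted p = 1.21e-06 and adjusted p = 0.139 with an estimated correlation. The 4 falls were those of hexokinase Hk2 (-1.13), the glucose transporter Slc2a3 (-1.49), the oxygen sensor Egln3 (-1.72) and the oxidoreductase Ero1a (-0.92). The Treg program did not pass as a list, and its members moved apart. For the Treg program the median was -0.18, with camera adjusted p = 0.208 and adjusted p = 0.620 with an estimated correlation. Il2ra (-1.40), the high-affinity IL-2 receptor chain, Tnfrsf9 (-1.83) and Tnfrsf18 (-0.72, outside the naming rule) fell, all known to rise on activated T cells as well. Il10 and Izumo1r (1.64), which encodes folate receptor 4, rose. Adjusted over the list alone 3 of its 18 members rose and 5 fell, and Foxp3, the Treg master regulator, differed by -0.22 ± 0.19 (adjusted p = 0.619). Among 14 tissue residency genes Cxcr6 (-0.86) and Rgs2 (-0.53) fell and 12 did not pass, with 5 lower when adjusted over the list alone. For tissue residency genes the median was -0.11, with camera adjusted p = 0.0608 and adjusted p = 0.273 with an estimated correlation.

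In the list of 16 naive and central memory T cell genes 7 rose and 9 did not pass. Counted with p adjusted over the list alone, 11 rose and 1 fell. For naive and central memory genes the median was 1.04, with camera adjusted p = 3.60e-09 and adjusted p = 0.151 with an estimated correlation. The rises included Dapl1, the transcription factor Lef1 (1.78) and S1pr1 (1.39), the receptor with which T cells leave tissue. Il6ra was also among them, with means of 8.87 in knockout and 7.02 in wild type. Ccr7, the lymph node homing receptor, was chosen after its value was seen (1.08). Of 12 Tfh program genes Cxcr5 (2.21), the follicle homing receptor, and Slamf6 (2.01) rose, the inhibitory receptor Pdcd1 (-1.36) fell and 9 did not pass. Adjusted over the list alone 7 were higher and 1 lower. For the Tfh program the median was 0.55, with camera adjusted p = 6.69e-05 and adjusted p = 0.139 with an estimated correlation. Bcl6, the Tfh master regulator, differed by 0.35 ± 0.18 (adjusted p = 0.386) and Il21, a Tfh cytokine, by 0.92 ± 0.27 (adjusted p = 0.148). Ccr7, S1pr1, Cxcr5 and Slamf6 are known from B cells too, whose markers had a median of 0.57 in the same comparison (adjusted p = 0.150 with an estimated correlation). Of 39 cell cycle genes 37 had a higher value, but only Rrm2 (1.16), a subunit of ribonucleotide reductase, rose past the threshold, over all genes as well as adjusted over the list alone. For cell cycle genes the median was 0.48, with camera adjusted p = 5.45e-10 and adjusted p = 0.295 with an estimated correlation, and the median was 0.25 without wild-type replicate 2.

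Of 23 Th1 and cytotoxic genes only Eomes (1.50), a transcription factor of memory and cytotoxic cells, rose and 22 did not pass. When adjusted over the list alone, 5 rose and 1 fell. For Th1 and cytotoxic genes the median was 0.29, with camera adjusted p = 0.0150 and adjusted p = 0.393 with an estimated correlation, and the median was 0.22 without wild-type replicate 1 (camera adjusted p = 0.0772) and 0.15 without knockout replicate 2. Ifng differed by 1.18 ± 0.44 (adjusted p = 0.248) and the Th1 master regulator Tbx21 by -0.15 ± 0.23 (adjusted p = 0.790). For Ifng wild-type replicate 1 lay at 8.20, apart from replicates 2 and 3 at 10.12 and 10.08. Of 31 type I interferon response genes Oas1a (0.76) rose and 30 did not pass, with 3 higher and 1 lower when adjusted over the list alone. For type I interferon response genes the median was 0.23, with camera adjusted p = 1.22e-04 and adjusted p = 0.170 with an estimated correlation. Of 13 heat shock and dissociation genes the chaperones Hspb1 (1.25) and Dnajb4 (0.91) rose and 11 did not pass, with 5 higher and 2 lower when adjusted over the list alone. For heat shock and dissociation genes the median was 0.26, with camera adjusted p = 0.00166 and adjusted p = 0.295 with an estimated correlation. Il17a differed by 0.68 ± 0.24 (adjusted p = 0.227), Il9 by -0.27 ± 0.12 (adjusted p = 0.326) and Bhlhe41, the closest relative of Bhlhe40, by -0.16 ± 0.18 (adjusted p = 0.704). Il1rl1, also on the fixed list of names, was not analysed here.

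Among markers of other cell types, of 10 plasma cell markers Jchain and Mzb1 (1.20) rose, also when adjusted over the list alone. For plasma cell markers the median was 0.30, with camera adjusted p = 1.20e-04 and adjusted p = 0.170 with an estimated correlation. Of 18 B cell markers Cd72 (1.33) rose, with 9 higher when adjusted over the list alone. For B cell markers the median was 0.57, with camera adjusted p = 2.11e-08 and adjusted p = 0.150 with an estimated correlation. None of 29 intestinal epithelium markers passed, and 2 rose adjusted over the list alone. For intestinal epithelium markers the median was 0.30, with camera adjusted p = 5.64e-04 and adjusted p = 0.295 with an estimated correlation. The keratin Krt8 had a difference of 3.96 ± 0.96 (adjusted p = 0.0915). Of 16 stroma and endothelium markers Acta2 and Pecam1 (1.37) rose, with 5 higher and 2 lower when adjusted over the list alone. The median of this list was -0.069 and its mean 0.44, of opposite sign, and camera gave the direction up (adjusted p = 0.131). Kit (1.74), the stem cell factor receptor, rose as the only one of 13 mast cell and basophil markers, whose median was -0.18 (camera adjusted p = 0.112).

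**Figure D2:**
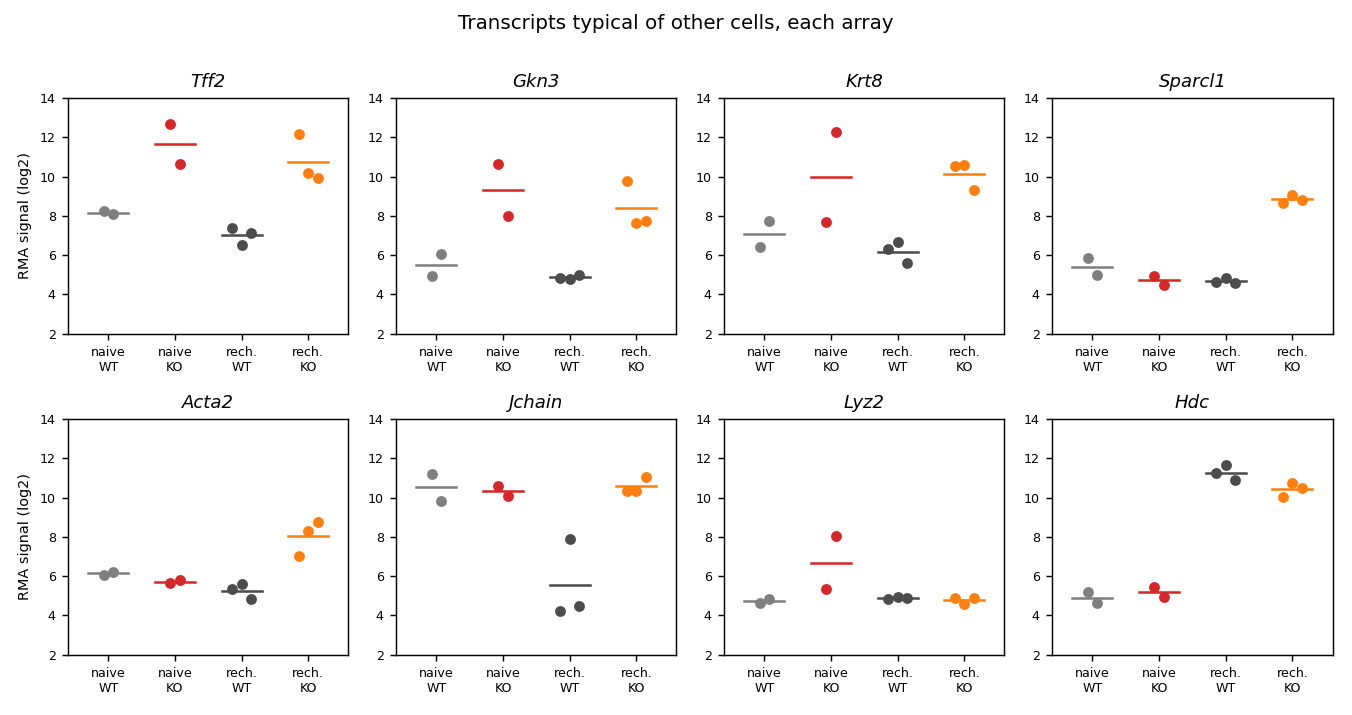
Each point is 1 array's RMA signal (log2, vertical axis) for 8 transcripts typical of other cells, with the 4 groups on the horizontal axis (rech., rechallenge, WT, wild type, KO, knockout) and lines at the group means. Tff2 and Gkn3 were higher in all 5 knockout arrays than in the 5 wild-type arrays, Sparcl1 averaged 8.84 in rechallenged knockout and between 4.68 and 5.40 in the other groups, and Jchain was lowest in rechallenged wild type with 4.25, 7.88 and 4.49.

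The other lists did not pass in this comparison. Their medians and camera adjusted p were 0.53 and 0.112 for the Th17 program, 0.19 and 0.0873 for cholesterol synthesis genes and -0.049 and 0.774 for TCR and AP-1 immediate early genes. They were -0.047 and 0.888 for oxidative phosphorylation genes, 0.084 and 0.888 for circadian clock genes and -0.045 and 0.663 for T cell identity genes. For markers of other cells they were 0.017 and 1 for macrophages and dendritic cells, -0.078 and 0.208 for eosinophils and neutrophils and 0.025 and 0.694 for CD8, gamma delta T and NK cells. Single members past the threshold were Hsd17b7 (-0.99) in cholesterol synthesis, Dusp2 (0.90) among the immediate early genes, Hlf (-0.87) among the clock genes and Trat1 (-1.10) among the T cell identity genes. Camera's direction was up although median and mean were negative for the immediate early and oxidative phosphorylation genes. For the macrophage markers the median was positive and the mean -0.0069.

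Of the 26 lists 12 passed with camera's preset correlation, 0 with an estimated correlation and 9 with fry, which tests whether the genes of a list move on balance one way without comparing them with other genes. The gene count was 89, 179, 68, 92 and 112 without wild-type replicate 1, wild-type replicate 3, knockout replicate 1, knockout replicate 2 and knockout replicate 3, 164 with a replicate block and 655 with array weights. With the epithelium and plasma cell covariates it was 2 (1488 genes at an unadjusted p under 0.05).

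The infection comparison in wild type asked what the rechallenge changes in CD4 T cells with an intact Bhlhe40 gene. Il13 rose 26.1-fold (4.71 ± 0.22, adjusted p = 9.37e-06) and Il4 11.5-fold (3.53 ± 0.24, adjusted p = 9.71e-05). Il5 (5.53 ± 0.24, adjusted p = 9.37e-06), Il6 (5.91 ± 0.54, adjusted p = 4.45e-04) and Hdc (6.37 ± 0.29, adjusted p = 9.37e-06), the enzyme that makes histamine, rose too, from naive means of 4.38, 3.90 and 4.90 that lie below the array medians, so the size of these rises is not measured exactly. Il23r, Il17a, Il10 and Jchain fell. The count was 679 genes, 404 up and 275 down, with 434 changed by at least 2-fold. The groups did not overlap for any of the 679, compared with 30.6% of all genes and 20% by chance.

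The 8 largest rises were Hdc, Il6, the histone gene H2bc4 (5.66 ± 0.75) and Il5. Slc17a6 (4.95 ± 0.31), Il13, the chemokine Ccl1 (4.51 ± 0.68) and Il1r2 (4.26 ± 0.34) completed them, with adjusted p up to 0.00610. H2bc4 (5.19) and Slc17a6 (5.01) too had naive means below the array medians, so the sizes and the order are not exact. The 8 largest falls were Jchain (-4.98 ± 0.92), Cd7 (-3.35 ± 0.60), and Jaml (-3.22 ± 0.39), an adhesion molecule of epithelial T cells. They also included the IL-23 receptor Il23r (-3.16 ± 0.55), the IL-12 receptor chain Il12rb2 (-2.94 ± 0.45), Dapl1 (-2.92 ± 0.57), Fcrl1 (-2.74 ± 0.38) and the kinase Txk (-2.70 ± 0.51), with adjusted p up to 0.0217. Jchain and Dapl1 fell to means below the array medians (5.54 and 5.53). Another 22 genes that passed are of kinds that the naming rule leaves out.

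Of 18 Th2 program genes 10 rose, 1 fell and 7 did not pass. Adjusted over the list alone 11 rose and 2 fell. The program's median was 2.45 and its mean 2.08 (camera adjusted p = 4.15e-13, and 0.00539 with an estimated correlation). Gata3 (2.57 ± 0.19, adjusted p = 1.39e-04) and Ccr8 (2.99 ± 0.13, adjusted p = 9.37e-06) were among the rises, and the fall was that of Hpgds (-1.11, chosen after its value was seen), a prostaglandin D2 synthase. Of the 31 cytokines and ligands 14 rose, 3 fell and 14 did not pass. With p adjusted over the list alone, 15 rose and 9 fell. For cytokines and ligands the median was 0.36, with camera adjusted p = 4.45e-05 and adjusted p = 0.0895 with an estimated correlation, and the median was 0.067 without naive replicate 1, 0.56 without naive replicate 2 and 0.20 without rechallenged replicate 2. Of the 8 CSF2RB family genes Csf2 (3.65 ± 0.31, adjusted p = 2.49e-04), Il3 (3.74 ± 0.40, adjusted p = 9.83e-04, from a naive mean of 3.72, below the array medians) and Il5 rose and 5 did not pass, as when adjusted over the list alone. For the CSF2RB family the median was 0.42, with camera adjusted p = 2.90e-05 and adjusted p = 0.0503 with an estimated correlation. Csf2rb differed by -0.50 ± 0.25 (adjusted p = 0.419). Il10 (-1.47 ± 0.22, adjusted p = 0.00544) and Il17a (-1.18 ± 0.27, adjusted p = 0.0464) were among the falls. Il9 (0.040 ± 0.13, adjusted p = 0.953) and Ifng (-1.11 ± 0.49, adjusted p = 0.348) did not pass. Neither did Il21 (-0.74 ± 0.30, adjusted p = 0.292) or Bhlhe41 (0.42 ± 0.20, adjusted p = 0.391). The Ifng value rests largely on rechallenged replicate 1, at 8.20 against 10.12 and 10.08 for replicates 2 and 3.

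The list of 21 glycolysis and hypoxia genes had 6 rises and 15 that did not pass. Counted with p adjusted over the list alone, it had 11 rises and 1 fall. For glycolysis and hypoxia genes the median was 0.62, with camera adjusted p = 2.02e-09 and adjusted p = 0.0503 with an estimated correlation. Egln3 rose by 2.22. The Treg program had 5 rises, such as Tnfrsf9 (2.11), a receptor of activated T cells, 3 falls and 10 members that did not pass. Foxp3 was among the falls (-1.16 ± 0.21, adjusted p = 0.0170). Adjusted over the list alone 9 rose and 3 fell. For the Treg program the median was 0.42, with camera adjusted p = 0.0250 and adjusted p = 0.448 with an estimated correlation, and the median was 0.28 without naive replicate 1, 0.33 without rechallenged replicate 1 (camera adjusted p = 0.0578) and 0.41 without rechallenged replicate 2 (camera adjusted p = 0.0536). Cholesterol synthesis genes had 6 falls, such as Lss (-0.77), 2 rises and 11 that did not pass. When adjusted over the list alone, there were 11 falls and 2 rises. For cholesterol synthesis genes the median was -0.59, with camera adjusted p = 5.89e-06 and adjusted p = 0.0895 with an estimated correlation, and the median was -0.35 without naive replicate 1. The rises were those of Sc5d and Hsd17b7.

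Th17 program genes had 4 falls of 9, Il23r, Il17a, Tmem176a (-2.10) and Tmem176b (-2.12), and 5 that did not pass. With p adjusted over the list alone, 7 fell and 1 rose. For the Th17 program the median was -1.18, with camera adjusted p = 8.78e-07 and adjusted p = 0.0895 with an estimated correlation. Among 31 interferon response genes 5 fell, such as Oas1a (-1.09) and the GTPases Iigp1 (-1.67) and Irgm1 (-1.60), and 26 did not pass, with 15 lower when adjusted over the list alone. For type I interferon response genes the median was -0.50, with camera adjusted p = 5.84e-09 and adjusted p = 0.0503 with an estimated correlation. Th1 and cytotoxic genes had 3 falls of 23, led by Il12rb2. Adjusted over the list alone they had 9 falls and 2 rises. For Th1 and cytotoxic genes the median was -0.50, with camera adjusted p = 0.00134 and adjusted p = 0.377 with an estimated correlation, and the median was -0.26 without rechallenged replicate 1. Tbx21 differed by 0.063 ± 0.26 (adjusted p = 0.961). Naive and central memory genes had 5 falls of 16, Dapl1, Txk and Lef1 (-1.84) among them. Counted with p adjusted over the list alone, they had 8 falls and 1 rise. For naive and central memory genes the median was -0.50, with camera adjusted p = 1.33e-05 and adjusted p = 0.229 with an estimated correlation, and the median was -0.79 without naive replicate 1 and -0.30 without naive replicate 2. The Tfh program had 2 falls (Cxcr5 and Slamf6) and 1 rise (Pdcd1) among 12. When adjusted over the list alone, it had 7 falls and 2 rises. For the Tfh program the median was -0.68, with camera adjusted p = 0.0106 and adjusted p = 0.225 with an estimated correlation, and the median was -0.61 without naive replicate 1 (camera adjusted p = 0.0523). Bcl6 differed by 0.052 ± 0.20 (adjusted p = 0.958). None of 39 cell cycle genes passed, over all genes or adjusted over the list alone. For cell cycle genes the median was -0.25, with camera adjusted p = 0.00201 and adjusted p = 0.649 with an estimated correlation, and the median was -0.59 without naive replicate 1, 0.050 without naive replicate 2 (camera adjusted p = 1), -0.40 without rechallenged replicate 1 and -0.11 without rechallenged replicate 2 (camera adjusted p = 0.407).

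Among markers of other cells the plasma cell list had 1 fall among 10, that of Jchain, and 2 falls adjusted over the list alone. For plasma cell markers the median was -0.26, with camera adjusted p = 0.0106 and adjusted p = 0.364 with an estimated correlation, and the median was -0.022 without naive replicate 1 (camera adjusted p = 0.386), -0.46 without naive replicate 2 and -0.16 without rechallenged replicate 1. The B cell list had 1 fall among 18, that of Cd72, as when adjusted over the list alone. For B cell markers the median was -0.13, with camera adjusted p = 0.0395 and adjusted p = 0.497 with an estimated correlation, and the median was 0.0077 without naive replicate 1 (camera adjusted p = 0.413), -0.27 without naive replicate 2, -0.16 without rechallenged replicate 1 (camera adjusted p = 0.0549) and -0.13 without rechallenged replicate 2 (camera adjusted p = 0.145). Hdc was the single rise among 13 mast cell and basophil markers, with 2 rises and 1 fall adjusted over the list alone. For mast cell and basophil markers the median was 0.094, with camera adjusted p = 0.0682 and adjusted p = 0.448 with an estimated correlation. None of 14 eosinophil and neutrophil markers passed. For eosinophil and neutrophil markers the median was 0.030, with camera adjusted p = 0.763 and adjusted p = 0.873 with an estimated correlation. The remaining lists did not pass, with camera adjusted p between 0.164 for oxidative phosphorylation and 0.922 for tissue residency genes.

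**Figure D3:**
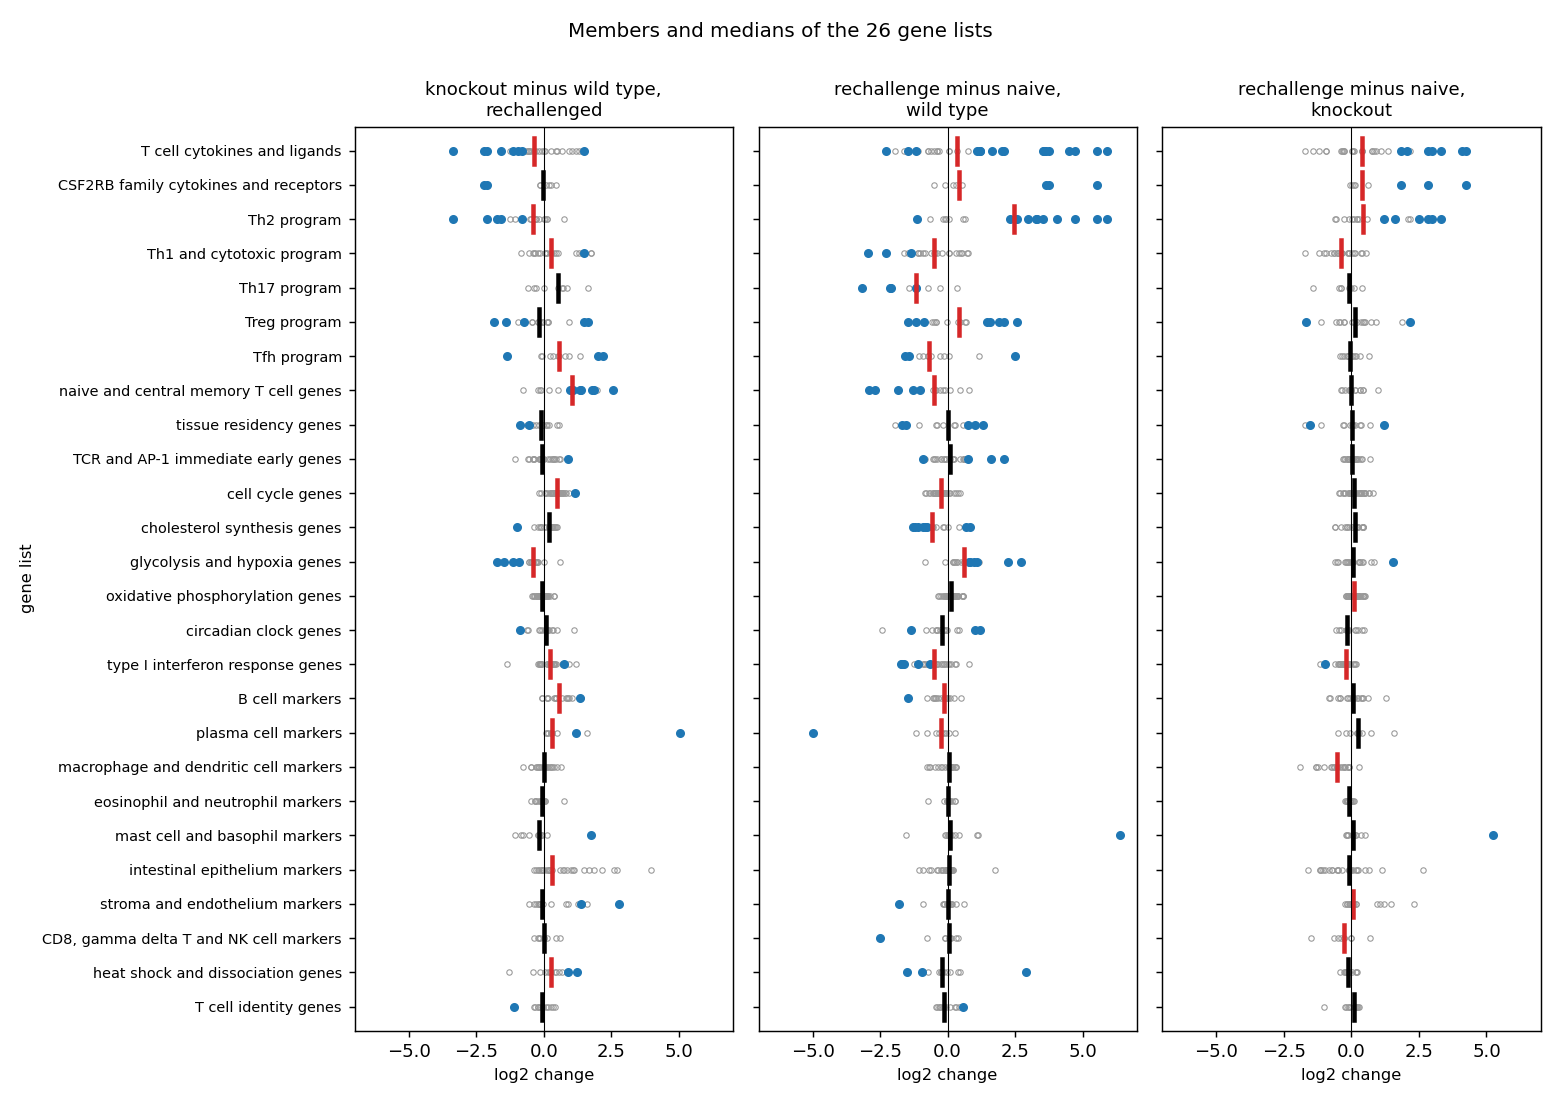
Each circle is 1 gene's log2 change (horizontal axis) on the gene lists named on the vertical axis, filled where the gene passed adjusted p 0.05 over all genes, in knockout against wild type after rechallenge and in rechallenge against naive in each genotype; vertical bars are list medians, red where camera with the preset correlation passed and black where not. Th2 program medians (means) were 2.45 (2.08) with infection in wild type, 0.42 (1.03) in knockout and -0.38 (-0.71) for knockout against wild type.

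With camera's preset correlation 14 lists passed, with fry 10 and with an estimated correlation 1, the Th2 program. The count of genes was 302, 279 and 446 without naive replicate 1, naive replicate 2 and rechallenged replicate 1, and 425 when only the arrays compared were fitted. It was 1026 without the naive knockout replicate 2 and the rechallenged wild-type replicate 2 and 131 with the epithelium and plasma cell covariates, the last 2 chosen after seeing the data.

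The genes lower in knockout were for the most part genes that infection raises in wild type. Of the 149 genes lower in knockout after rechallenge 129 were among the 404 that rose in wild type, with 3.03 expected if the lists were independent. Of the 127 higher genes 73 were among the 275 that fell, with 1.76 expected. No gene was shared in the opposite pairings. Il5, Il13, Csf2, Il6 and Alox5 belong to the former set and Jchain, Dapl1 and Lef1 to the latter. Both comparisons use the same 3 rechallenged wild-type arrays. Across genes, which are not independent replicates, the covariance of the changes was -0.102, with -0.0180 simulated from the shared arrays alone (100 data sets without any true change). When the rechallenged wild-type arrays were split so that none entered both changes, a test chosen after seeing the data, the covariance lay between -0.0922 and -0.0665 over the 6 ways to split them.

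The infection comparison in knockout asked the same of cells without an intact Bhlhe40 gene. Among type 2 cytokines Il4 rose by 2.99 ± 0.24 (adjusted p = 0.001004, 7.95-fold) and Il13 by 3.32 ± 0.22 (adjusted p = 3.30e-04). Il5 rose by 2.83 ± 0.24 (adjusted p = 0.00134) and Il3 by 4.24 ± 0.40 (adjusted p = 0.00259). Hdc rose as well (5.25 ± 0.29, adjusted p = 2.03e-04), and the naive means of Il5, Il3 and Hdc (4.99, 3.69 and 5.18) lie below the array medians. Only 65 genes passed, 53 up and 12 down, 61 of them by at least 2-fold. The groups did not overlap for any of the 65, compared with 25.8% of all genes and 20% by chance. Of the 53 rises 43 were also rises in wild type (1.08 expected if independent). Of the 12 falls 4 were also falls (0.166 expected). These comparisons share no array.

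The other large rises were Sparcl1 (4.13 ± 0.25), Ccl1 (4.11 ± 0.68), the amino acid transporter Slc7a8 (3.21 ± 0.43) and Tmem273 (3.13 ± 0.45). The 8 largest falls were Hpgd (-1.86 ± 0.19), which degrades prostaglandins, Ky (-1.77 ± 0.29), Foxp3 (-1.67 ± 0.21) and the cytokine Il1b (-1.67 ± 0.18). They also included the gut homing receptor Ccr9 (-1.55 ± 0.23), the integrin Itgb8 (-1.53 ± 0.24), Nap1l3 (-1.41 ± 0.21) and Chordc1 (-1.17 ± 0.17), with adjusted p up to 0.0440. Sparcl1 rose from a naive mean below the array medians (4.72), and Hpgd, Ky, Il1b and Nap1l3 fell to such means (4.87, 5.56, 5.10 and 5.16), so these sizes and their order are not exact.

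Of 18 Th2 program genes 6 rose and 12 did not pass, and adjusted over the list alone 8 rose. The program's median was 0.42 and its mean 1.03 (camera adjusted p = 5.97e-10, and 0.0115 with an estimated correlation). Without naive replicate 2 the median was 0.64. Of 31 cytokines and ligands 7 rose and 24 did not pass, with 15 higher and 3 lower when adjusted over the list alone. For cytokines and ligands the median was 0.39, with camera adjusted p = 7.77e-07 and adjusted p = 0.0600 with an estimated correlation. Csf2 (1.85 ± 0.31), Il3 and Il5 rose among the 8 CSF2RB family genes, with 4 rises adjusted over the list alone. For the CSF2RB family the median was 0.38, with camera adjusted p = 3.83e-06 and adjusted p = 0.0307 with an estimated correlation. Of 31 interferon response genes Oas1a fell and 30 did not pass, with 2 lower adjusted over the list alone. For type I interferon response genes the median was -0.21, with camera adjusted p = 7.39e-04 and adjusted p = 0.225 with an estimated correlation, and the median was -0.13 without naive replicate 1, -0.33 without naive replicate 2 and -0.39 without rechallenged replicate 3. None of 23 Th1 and cytotoxic genes passed, with 1 lower adjusted over the list alone. For Th1 and cytotoxic genes the median was -0.38, with camera adjusted p = 0.00379 and adjusted p = 0.578 with an estimated correlation, and the median was -0.21 without naive replicate 1. None of 44 oxidative phosphorylation genes passed either way. For oxidative phosphorylation genes the median was 0.11, with camera adjusted p = 0.0400 and adjusted p = 0.774 with an estimated correlation, and the median was -0.17 without naive replicate 1 (camera adjusted p = 0.00918), 0.35 without naive replicate 2 and 0.091 without rechallenged replicate 3 (camera adjusted p = 0.236). Of 21 macrophage and dendritic cell markers none passed over all genes and 5 were lower adjusted over the list alone. For macrophage and dendritic cell markers the median was -0.52, with camera adjusted p = 2.13e-07 and adjusted p = 0.0437 with an estimated correlation. The naive knockout replicate 2 had the highest mean of this list, 6.10, while the other arrays lay at or under 5.85. The stroma and endothelium list passed with 3 rises adjusted over the list alone and none over all genes. For stroma and endothelium markers the median was 0.065, with camera adjusted p = 0.0454 and adjusted p = 0.234 with an estimated correlation, and without 1 array the median ran from -0.035 to 0.14, with camera adjusted p = 0.451 without naive replicate 2 and 0.0560 without rechallenged replicate 2. The CD8, gamma delta T and NK cell list had 2 falls adjusted over the list alone and none over all genes. For CD8, gamma delta T and NK cell markers the median was -0.28, with camera adjusted p = 0.0490 and adjusted p = 0.225 with an estimated correlation, and the median was -0.43 without naive replicate 1 (camera adjusted p = 0.0680), -0.21 without naive replicate 2 (camera adjusted p = 0.189), -0.20 without rechallenged replicate 1 (camera adjusted p = 0.0745) and -0.32 without rechallenged replicate 2 (camera adjusted p = 0.107). The calls of the Th2 program, the CSF2RB family and the macrophage markers held with an estimated correlation, 3 of the 9 that camera gave, and fry gave 5.

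The count was 219 without naive replicate 2, 235 without naive replicate 1 and 39, 30 and 43 without rechallenged replicates 1, 2 and 3, 22 when only the arrays compared were fitted and 41 with a replicate block. Of alternatives chosen after seeing the data, leaving out the naive knockout replicate 2 and the rechallenged wild-type replicate 2 gave 273 and the epithelium and plasma cell covariates gave 100.

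Genotype in naive mice was compared to ask what the knockout changes without infection. No gene passed limma's test (smallest adjusted p 0.102), with 1341 genes at an unadjusted p under 0.05 where 995 are expected by chance. Of all genes 31.2% had no overlap between the groups, and 33.3% do by chance. The largest differences, none past the threshold, were Clu (3.97 ± 0.56), Gkn3 (3.81 ± 0.87), Tff2 (3.51 ± 0.77), Cd63 (2.37 ± 0.45) and Gsta4 (2.16 ± 0.53) among higher values. Lower values were those of Rab11fip2 (-2.35 ± 0.28), Plekha1 (-1.90 ± 0.39), Olfr60 (-1.90 ± 0.35), Slc25a32 (-1.82 ± 0.39) and Srgap3 (-1.81 ± 0.41). On simulated data the same design recovered 64% of changes of 1 and 98% of changes of 2. The simulation gave all groups the same spread per gene and independent noise. The 2 naive knockout arrays differed from each other by an SD of 0.49 over genes, against 0.33 for the naive wild-type pair. Recovery in the real naive arrays may therefore be lower, and the lack of calls does not exclude large naive differences.

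Of the 26 lists 9 passed with camera, 0 with an estimated correlation and 0 with fry, and no member passed over all genes. Lower in knockout, adjusted over the list alone, were 5 of 19 cholesterol synthesis genes, 3 of 9 Th17 program genes and 0 of 14 tissue residency genes. For cholesterol synthesis genes the median was -0.50, with camera adjusted p = 3.40e-07 and adjusted p = 0.0957 with an estimated correlation, and the median was -0.28 without wild-type replicate 1 and -0.28 without knockout replicate 2. For the Th17 program the median was -0.88, with camera adjusted p = 6.03e-04 and adjusted p = 0.253 with an estimated correlation. For tissue residency genes the median was -0.27, with camera adjusted p = 0.0284 and adjusted p = 0.240 with an estimated correlation, and the median was -0.24 without wild-type replicate 1 (camera adjusted p = 0.126) and -0.22 without knockout replicate 1 (camera adjusted p = 0.392). Higher in knockout, adjusted over the list alone, were 2 of 18 Th2 program genes, 1 of 12 Tfh program genes and 0 of 13 heat shock genes. For the Th2 program the median was 0.41, with camera adjusted p = 0.00207 and adjusted p = 0.0957 with an estimated correlation, and the median was 0.14 without wild-type replicate 2, 0.13 without knockout replicate 1 and 0.23 without knockout replicate 2. For the Tfh program the median was 0.31, with camera adjusted p = 0.00875 and adjusted p = 0.240 with an estimated correlation, and the median was 0.31 without wild-type replicate 2 (camera adjusted p = 0.0857) and 0.23 without knockout replicate 2 (camera adjusted p = 0.225). For heat shock and dissociation genes the median was 0.23, with camera adjusted p = 0.00207 and adjusted p = 0.390 with an estimated correlation, and the median was 0.13 without wild-type replicate 2 (camera adjusted p = 0.204) and 0.082 without knockout replicate 2 (camera adjusted p = 0.390). Markers of other cells had higher values too, and adjusted over the list alone 0 of 21 rose for macrophages and dendritic cells, 0 of 29 for epithelium and 2 of 18 for B cells. For macrophage and dendritic cell markers the median was 0.42, with camera adjusted p = 1.10e-06 and adjusted p = 0.0957 with an estimated correlation. For intestinal epithelium markers the median was 0.53, with camera adjusted p = 1.14e-06 and adjusted p = 0.240 with an estimated correlation, and the median was 0.84 without knockout replicate 1 and 0.085 without knockout replicate 2 (camera adjusted p = 0.381). For B cell markers the median was 0.19, with camera adjusted p = 0.0157 and adjusted p = 0.512 with an estimated correlation, and the median was 0.30 without wild-type replicate 1, 0.21 without wild-type replicate 2 (camera adjusted p = 0.124), -0.0021 without knockout replicate 1 (camera adjusted p = 0.590) and 0.45 without knockout replicate 2.

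The macrophage marker Lyz2 was at 8.06 and Krt8 at 12.28 in naive knockout replicate 2, against 5.33 and 7.67 in replicate 1. The gene count was 67 without naive knockout replicate 2, 213 without replicate 1, 1 without naive wild-type replicate 1, 1 when only the arrays compared were fitted and 3 with a trended and robust variance. Of alternatives chosen after seeing the data, leaving out the naive knockout replicate 2 and the rechallenged wild-type replicate 2 gave 51 and the covariates gave 13.

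The interaction asked whether the genotype effect differed between rechallenged and naive mice, which is the test of the difference itself. It passed for 19 genes, 4 with a more positive and 15 with a more negative genotype effect after rechallenge, and all 19 differed by at least 2-fold. The most negative were Slc17a6 (-3.47 ± 0.44), Ccr1 (-3.42 ± 0.48), the inhibitory receptor Havcr2 (-3.31 ± 0.46), Nlrp3 (-3.17 ± 0.32) and Alox5 (-2.87 ± 0.38). Next came the prohormone convertase Pcsk1 (-2.85 ± 0.35), Il5 (-2.70 ± 0.34) and Tnfrsf9 (-2.67 ± 0.30), and the 8 had adjusted p from 0.0136 to 0.0479. In naive mice the means of both genotypes lay below all array medians for 7 of the 19 (Slc17a6, Ccr1, Nlrp3, Alox5, Il5, Cyp11a1 and Sparcl1), where a genotype effect could hardly show, so for these the test largely restates the difference after rechallenge. The positive ones were Sparcl1 (4.85 ± 0.35), Actn1 (3.16 ± 0.31), AI987944 (2.11 ± 0.29) and Dyrk2 (1.16 ± 0.17). Jchain (5.22 ± 1.30), Dapl1 (3.24 ± 0.80) and Acta2 (3.19 ± 0.59) had large values that did not pass. Il13 (-1.39 ± 0.31, adjusted p = 0.134), Csf2 (-1.80 ± 0.44, adjusted p = 0.166) and Il6 (-3.75 ± 0.77, adjusted p = 0.105) did not pass, so a genotype effect limited to infection is not shown for them.

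Of 26 lists 10 passed with camera, and the Th2 program alone passed with an estimated correlation and with fry. With p adjusted over the list alone, 9 of its 18 genes had a more negative genotype effect after rechallenge and 1 a more positive one. The program's median was -0.89 and its mean -1.05 (camera adjusted p = 5.78e-06, and 0.0443 with an estimated correlation). The effect was also more negative for 4 of 21 glycolysis and hypoxia genes (more positive for 1) and for 0 of 21 macrophage and dendritic cell markers. For glycolysis and hypoxia genes the median was -0.45, with camera adjusted p = 1.50e-05 and adjusted p = 0.198 with an estimated correlation, and the median was -0.75 without naive knockout replicate 1. For macrophage and dendritic cell markers the median was -0.47, with camera adjusted p = 9.57e-04 and adjusted p = 0.198 with an estimated correlation. The effect was more positive for 6 of 16 naive and central memory genes, 3 of 19 cholesterol synthesis genes and 5 of 9 Th17 program genes (more negative for 1). For naive and central memory genes the median was 0.78, with camera adjusted p = 8.49e-06 and adjusted p = 0.348 with an estimated correlation, and the median was 0.41 without naive knockout replicate 2. For cholesterol synthesis genes the median was 0.51, with camera adjusted p = 8.49e-06 and adjusted p = 0.198 with an estimated correlation. For the Th17 program the median was 1.19, with camera adjusted p = 0.00126 and adjusted p = 0.348 with an estimated correlation. A more positive effect was found for 0 of 39 cell cycle genes, 0 of 31 interferon response genes, 2 of 10 plasma cell markers and 2 of 18 B cell markers. For cell cycle genes the median was 0.40, with camera adjusted p = 1.47e-04 and adjusted p = 0.551 with an estimated correlation, and the median was 0.68 without naive wild-type replicate 1, 0.068 without naive wild-type replicate 2 (camera adjusted p = 0.260), 0.24 without naive knockout replicate 1 (camera adjusted p = 0.0646) and 0.18 without rechallenged wild-type replicate 2. For type I interferon response genes the median was 0.30, with camera adjusted p = 0.00566 and adjusted p = 0.348 with an estimated correlation, and the median was 0.23 without naive knockout replicate 2 (camera adjusted p = 0.0758). For plasma cell markers the median was 0.47, with camera adjusted p = 0.00608 and adjusted p = 0.364 with an estimated correlation, and the median was 0.22 without naive wild-type replicate 1 (camera adjusted p = 0.0983), 0.77 without naive wild-type replicate 2, 0.71 without naive knockout replicate 1 and 0.34 without rechallenged knockout replicate 1 (camera adjusted p = 0.0524). For B cell markers the median was 0.15, with camera adjusted p = 0.0330 and adjusted p = 0.505 with an estimated correlation, and without 1 array the median ran from 0.0052 to 0.31, with camera adjusted p = 0.199 without naive wild-type replicate 1, 0.345 without naive knockout replicate 2, 0.119 without rechallenged wild-type replicate 2, 0.0524 without rechallenged knockout replicate 1 and 0.103 without rechallenged knockout replicate 3.

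The gene count ranged from 2 without naive wild-type replicate 2, or without rechallenged knockout replicate 2, to 179 without naive knockout replicate 1. It was 99 without naive knockout replicate 2, 7 without naive wild-type replicate 1, and 37, 11 and 11 without rechallenged wild-type replicates 2, 1 and 3. Without rechallenged knockout replicates 1 and 3 it was 8 and 12, and 1 with a replicate block. Of alternatives chosen after seeing the data, leaving out the naive knockout replicate 2 and the rechallenged wild-type replicate 2 gave 138 and the epithelium and plasma cell covariates gave 0, with 1462 genes at an unadjusted p under 0.05.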

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

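The tests of a lower share of Th2 cells, of dilution, of the sources of Tff2 and Jchain and of mast cells, basophils, neutrophils or eosinophils were chosen only after the result was seen, as was the covariate alternative. The splits of the arrays were planned. Groups of 2 or 3 arrays were not tested for single arrays that stand apart.

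A difference between the genotype effects in rechallenged and naive mice passed the interaction test for 19 genes. It was negative for Slc17a6 (-3.47), Ccr1 (-3.42), Havcr2 (-3.31), Nlrp3 (-3.17), Alox5 (-2.87), Pcsk1 (-2.85), Il5 (-2.70), Tnfrsf9 (-2.67), Cyp11a1 (-2.48), Tent5a (-2.46), Klrg1 (-2.34), Ifitm2 (-2.21), Hpgd (-1.92), Pdcd1 (-1.87) and Ccr8 (-1.78). It was positive for Dyrk2 (1.16), AI987944 (2.11), Actn1 (3.16) and Sparcl1 (4.85). For 7 of them (Slc17a6, Ccr1, Nlrp3, Alox5, Il5, Cyp11a1 and Sparcl1) both naive means lay below all array medians, so the test there rests largely on the rechallenged arrays. Some of the 19 had opposite signs in the 2 conditions: Havcr2 differed by -1.53 between genotypes after rechallenge and by 1.78 in naive mice, and Hpgd by -0.20 and 1.72.

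Of the gene lists, the same test of the difference passed with camera for the Th2 program (median -0.89), glycolysis and hypoxia genes (-0.45), macrophage and dendritic cell markers (-0.47), the Th17 program (1.19), naive and central memory T cell genes (0.78), cell cycle genes (0.40), cholesterol synthesis genes (0.51), type I interferon response genes (0.30), B cell markers (0.15) and plasma cell markers (0.47). With an estimated correlation the Th2 program held and the other 9 calls were lost (adjusted p = 0.198 to 0.551 with an estimated correlation). Among the 5287 probe sets that the annotation pairs with no gene or with several, which enter no comparison, 13 passed between genotypes in rechallenged mice and 59 with infection in wild type.

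Il5, Il13, Csf2 and Il6 were lower in rechallenged knockout arrays (-2.09, -1.57, -2.23 and -3.37) while Il4 differed by 0.030. The 10 splits of the 6 rechallenged arrays are too few for a share under 0.05. The real split gave 276 genes and the highest other 0, so the 1 split with as many genes is the real one itself. A lower share of Th2 cells would lower other Th2 genes about as much as Il13 if all came from those cells alone. The mean change of the 7 other Th2 program genes that rose with infection lay 0.78 ± 0.22 (SE) above that of Il13. The 95% lower bound was 0.29 over arrays and 0.21 over these genes, which ran from -1.71 for Plac8, below Il13, to 0.030 for Il4. On that condition this argues against a lower share as the whole cause. Gata3, Il4 and Plac8 were already at 9.99, 9.35 and 9.28 in naive wild type, against 7.02 for Il13, so the condition is not shown to hold for them. The mean change of the 7 genes was still -0.79, so a lower share may be part of the cause. Dilution by RNA of other cells would lower T cell identity genes alike, and their median change was -0.045 (SD 0.40 over 13 genes) against -1.57 for Il13. Open, as a hypothesis, is that the genotype itself lowers these messages in the cells; with the epithelium and plasma cell covariates Il5 went from -2.09 ± 0.22 to -1.06 ± 0.30, Il13 from -1.57 ± 0.20 to -0.93 ± 0.37, Csf2 from -2.23 ± 0.28 to -1.06 ± 0.45 and Il6 from -3.37 ± 0.49 to -3.47 ± 1.13. All 4 calls ended, with a smaller change for the first 3 but not for Il6, and with a median SE of all genes of 0.31 in place of 0.15. Residual degrees of freedom were 4 in place of 6. The epithelium mean lay at 5.08 to 5.22 on wild-type arrays and at 5.36 to 6.82 on knockout arrays, without overlap. Within a group it differed most between the naive knockout arrays (5.36 and 6.82). The fit thus separates the genotype from this signal poorly, and the smaller changes do not show that carried-over cells cause the difference.

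Transcripts of other cell types differed between genotypes: Tff2 and Gkn3 were high in all 5 knockout arrays, Sparcl1 and Acta2 in the rechallenged knockout arrays, and Jchain was low in the rechallenged wild-type arrays 1 and 3. The difference of Tff2 and Gkn3 had an SD of 0.25 over the 5 knockout arrays, against 1.24 for Tff2 itself, consistent with 1 mucous gland source carried through the CD4 sort. Krt8-bearing epithelium is not that source by this measure, since Tff2 minus Krt8 had an SD of 2.54. Whether IgA plasma cells are the source of Jchain in the rechallenged knockout arrays 2 and 3 stays open: Igha was 10.73 in array 1, and the higher of these 2 lay at -0.46 from the highest rechallenged wild-type array, but it is 1 transcript, it was as low (5.07) in naive wild-type arrays with Jchain at 11.19 and 9.84, and Mzb1 rose beside Jchain. B cell markers were higher too in the rechallenged knockout arrays (median 0.57, adjusted p = 0.150 with an estimated correlation), and what stays open, untested, is whether B cells add to the higher Ccr7, S1pr1, Cxcr5 and Slamf6 there, and whether these cells differ because of the genotype, the dissection or the sort, which the design does not separate.

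Hdc, Il1r2, Alox5, Ccr1, Nlrp3 and Cxcl2, known from mast cells, basophils and myeloid cells, rose with infection in wild type (Hdc 6.37, Il1r2 4.26, Alox5 3.34, Ccr1 3.24, Nlrp3 2.97, Cxcl2 3.74; the last 4 were chosen after their values were seen). Mast cells or basophils in the sort would bring their other transcripts, but the median change of the 12 other markers, none of them on another list, was 0.069 (SE of the median 0.24), that of 5 of them known from basophils 0.094 (SE 0.28) and the median of the 14 eosinophil and neutrophil markers was 0.030 (SE 0.079). These medians argue against such cells as the whole source, under a CD4 sort that would remove most of them. The basophil protease Mcpt8 had 1.13 ± 0.33 (adjusted p = 0.120), and fry for the list with Hdc gave an adjusted p of 0.0112, so a small share of basophils stays open. A candidate explanation left open is that the T cells themselves express these genes, which arrays of sorted cells do not test.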

How the results depend on the processing

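The alternatives that left out the naive knockout array 2, alone or with the rechallenged wild-type array 2, and those with covariates were chosen only after the result was seen, and all other tests here were planned. Where a value changed, the cause was not tested unless stated. The mean of a gene's probe sets changes the values of only 885 of the 19898 genes, so most results could hardly move with it. Of the named genes and called lists, 240 results kept direction (for lists, that of camera) and side of the threshold and 0 lost the call with the mean of a gene's probe sets, 238 and 2 with arrays centred on their medians, 220 and 19 with a repeated quantile normalization, 223 and 11 without dim genes, 181 and 4 with a trended and robust variance, 173 and 11 with array weights and 136 and 23 with only the arrays compared. It was 190 kept and 50 lost with the replicate block, 219 and 15 without the naive knockout array 2, 208 and 22 without both arrays, 74 and 106 with the covariates and, for lists, 5 and 49 with an estimated correlation and 22 and 32 with fry. Leaving out 1 array kept 1052 and lost 378, as it also leaves fewer samples. Signal over background limits dim genes, and 10940 genes were left without them.

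The genotype count in rechallenged mice, 276, was 159 with a minimum log2 change of 1 (fewer genes by construction), 655 with array weights, 441 without the naive knockout array 2 and the rechallenged wild-type array 2, 2 with the covariates and 68 to 289 without 1 array. The genotype count in naive mice, 0 with 1341 genes at an unadjusted p under 0.05, was 1 with only the arrays compared, 3 with a trended and robust variance, 67 without the naive knockout array 2, 51 without both arrays, 13 with the covariates and 0 to 213 without 1 array. The infection count in wild type, 679, was 434 with the minimum change, 425 with only the arrays compared, 1026 without both arrays, 131 with the covariates and 279 to 775 without 1 array. The infection count in knockout, 65, was 22 with only the arrays compared, 219 without the naive knockout array 2, 273 without both arrays, 100 with the covariates and 30 to 235 without 1 array. The interaction count, 19, was 99 without the naive knockout array 2, 138 without both arrays, 0 with the covariates and 2 to 179 without 1 array. The direction of the counts moved too. Infection in knockout went from 53 up and 12 down to 72 up and 163 down without naive replicate 1 and 146 and 73 without naive replicate 2, and infection in wild type from 404 and 275 to 485 and 541 without both arrays. The interaction went from 4 up and 15 down to 53 and 46 without the naive knockout array 2, 71 and 67 without both arrays, 47 and 132 without naive knockout replicate 1, 4 and 3 without naive wild-type replicate 1 and 10 and 18 with arrays centred on their medians. Genotype in rechallenged mice went from 127 and 149 to 241 and 200 without both arrays, 151 and 138 without wild-type replicate 2 and 146 and 142 with arrays centred on their medians. The replicate numbers as a block, which the labels do not state to pair the samples, gave 164 in place of 276, 41 in place of 65 and 1 in place of 19.

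Of the lists, camera with an estimated correlation gave 0 in place of 12 and 0 in place of 9 between genotypes in rechallenged and naive mice, 1 in place of 14 and 3 in place of 9 with infection in wild type and knockout and 1 in place of 10 for the interaction. Fry gave 0 for naive mice, 5 for infection in knockout and 1 for the interaction. Without 1 array the list counts ran from 12 to 16 and 7 to 11 between genotypes, 11 to 15 and 8 to 12 with infection and 8 to 12 for the interaction. Bhlhe40 ran from -1.68 to -1.48 in rechallenged and -0.47 to -0.37 in naive mice, 1.53 to 1.72 and 0.42 to 0.55 with infection and -1.26 to -1.06 for the interaction. With the covariates it was -1.50 ± 0.31 (SE) in rechallenged mice, at an adjusted p of 0.291 (0.000671 to 0.291 over its alternatives), where the SE grew from 0.13.

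Small changes that had not passed turned sign. Between genotypes in rechallenged mice Il4 was -0.040 without wild-type replicate 1 (-0.040 to 0.071 without 1 array) and Tbx21 0.010 without wild-type replicate 2, alone or with the naive knockout array 2 (-0.28 to 0.010 without 1 array). With the covariates Bhlhe41 was 0.37, Foxp3 0.059, Il9 0.11 and Tbx21 0.11. With infection in wild type Bcl6 was -0.14 without naive replicate 2 and -0.035 without rechallenged replicate 2, alone or with the naive knockout array 2 (-0.14 to 0.24 without 1 array). Tbx21 was -0.012 with array weights, -0.12 without naive replicate 2 and -0.097 without rechallenged replicate 2, alone or with the naive knockout array 2 (-0.12 to 0.24 without 1 array). Il9 was -0.023 with a repeated quantile normalization, -0.019 without naive replicate 1 (-0.019 to 0.098 without 1 array) and -0.12 with the covariates, and Bhlhe41 -0.0095 with the covariates. Of called lists, the oxidative phosphorylation genes with infection in knockout turned past the threshold, with a median of -0.17 without naive replicate 1 (-0.17 to 0.35 without 1 array), and had -0.0053 with the replicate block, no longer past it. Other medians turned where the call ended. With infection these were the cell cycle genes (0.050 without naive replicate 2) and B cell markers (0.0077 without naive replicate 1) in wild type and the stroma and endothelium markers (-0.035 without naive replicate 2) in knockout. Between genotypes they were the B cell markers in naive mice (-0.0021 without knockout replicate 1) and for the interaction (-0.047 without dim genes).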

Other observations

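None of the tests in this part was chosen only after its result was seen, but the genes of the next paragraphs were named after their values were seen.

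The leukotriene B4 receptor Ltb4r1 rose by 2.29 ± 0.17 with infection in wild type (adjusted p = 1.39e-04) and was -1.66 ± 0.15 in knockout against wild type after rechallenge (adjusted p = 0.00194). The histamine receptor Hrh4 had 2.27 ± 0.31 and -1.73 ± 0.28 (adjusted p = 0.00346 and 0.0195), and Ffar2, a receptor for short-chain fatty acids, 2.70 ± 0.15 and -1.22 ± 0.13 (adjusted p = 3.58e-05 and 0.00361).

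Of the genes for interferon-induced membrane proteins, Ifitm1 rose by 2.39 ± 0.33, Ifitm2 by 2.87 ± 0.18 and Ifitm3 by 3.16 ± 0.52 in wild type (adjusted p = 0.00367, 6.19e-05 and 0.00918). In knockout against wild type after rechallenge Ifitm1 (-1.91 ± 0.29, adjusted p = 0.0177) and Ifitm2 (-1.75 ± 0.16, adjusted p = 0.00203) were lower, and Ifitm3 did not pass (-1.22 ± 0.47, adjusted p = 0.260).

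A hypothesis is that knockout cells respond to infection with a smaller change of the genes that move most in wild type. The 200 largest rises and the 200 largest falls were picked on 3 of the 5 wild-type arrays and measured on the other 2 and on the 5 knockout arrays, for all 6 choices. The 200 rises had medians of 1.84 to 2.08 in the held-out wild-type arrays and 0.68 to 0.76 in knockout, a ratio of 0.347 to 0.385, and the 200 falls had medians of -1.15 to -0.80 and -0.18 to -0.10, a ratio of 0.102 to 0.193. The highest ratio, 0.385, was under the set 0.8. These genes thus changed less in knockout, in the cells or in what the sort held beside them. None was picked in knockout, so an equally large but different response stays open.

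Another hypothesis is that part of the genotype calls in rechallenged mice comes from DNA next to the targeted gene that differs between the genotypes, as can remain after crossing a targeted line to another strain. Of the 100 tested genes next to Bhlhe40 on its chromosome, 50 on each side, 4 passed (Lrig1 1.02, Foxp1 0.99, Crbn -1.50 and Fancd2 0.74), 4% against 1.37% of all other genes. The exact Fisher p was 0.05004, just over the threshold set for this test, so these counts leave the question open; the labels name C57BL/6 as the background strain.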
